A study of Arabidopsis thaliana with 18 samples.

How the data were processed

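Total RNA from rosette leaves of wild type and drl1 plants at 0, 6 and 48 h after inoculation was labelled and hybridized to Agilent 2-colour arrays, with 3 samples in each of 6 groups. Every sample is one channel of an array: 14 samples carried Cy5 and 4 carried Cy3 (replicate 3 at 6 h and replicate 1 at 48 h, in both genotypes). The other channel of 10 arrays belongs to no sample of the study and was not used, and 4 arrays held 2 samples each. Within each genotype, replicates 1 and 3 at 48 h shared an array, as did replicate 3 at 6 h and replicate 2 at 48 h. Arrays lay on 4 slides, scanned on 1 day. Replicate 1 at 0 h had a slide of its own, replicates 2 and 3 at 0 h shared the second, replicates 1 and 2 at 6 h the third, and replicate 3 at 6 h and all 48 h samples the fourth. Samples of both genotypes with the same time and number shared slide and dye.

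Per the file headers, spot values came from Agilent Feature Extraction 10.1.1.1 and are an intensity on a linear scale: the mean of the spot and the median of its local background, without normalization, and a processed signal that the scanner software had background-subtracted, detrended and dye-normalized. The deposited table of values by the authors is on a log2 scale, made with limma according to their notes and not centred. It was checked against normexp correction followed by quantile normalization within each dye, with correlations of 0.9995 for Cy5 and 0.9982 for Cy3, and entered as an alternative only. Per the file headers, other columns are 0 or 1 marks of the scanner software for spots well above background, saturated or outlying.

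Background was corrected with limma's normexp (offset 50) on the mean spot and median background intensities of the sample's own channel over all spots. The log2 values were quantile-normalized across the 18 channels. Spots marked as outliers were set to missing (0.043% to 4.94% of the spots per sample, and 3.21% of the values of the genes tested), and no spot was saturated. The share was 0.043% to 0.096% in Cy3 samples and 0.73% to 4.94% in Cy5 samples, so missing values follow the dye. At 6 h and 48 h the only values of PAD3 in drl1, and of WRKY33 in both genotypes, were from Cy3 samples. The arrays held 45220 spots, of which 1417 were controls and were dropped. Spots of the same probe were averaged. Of 43603 probes, 37540 match 1 locus in the array annotation, 873 match several and 5190 none, and only the first kind was used. The platform annotation gave the loci, and a reference table of locus tags gave the symbols (10123 loci with a symbol, 159 symbols used for 2 loci). A probe had to be well above background in at least 3 of 18 samples and have at least 1 value in each group. The brightest probe stood for a locus with several (6453 genes), which left 20369 genes. The share of spots well above background and the median intensity (88.1 to 165 per sample over a background of 24 to 42) describe the depth, and the number of arrays limits the precision. The median SE of a genotype or time difference was 0.105 to 0.117 over the comparisons, and 0.154 and 0.163 for the interactions.

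A linear model with a mean for each of the 6 groups and a term for dye was fitted with limma, with the array as a random effect (correlation 0.75 by duplicateCorrelation) and a trended prior variance, at 11 residual degrees of freedom. From it came 9 contrasts: drl1 against wild type at each time, 6 h and 48 h against 0 h in each genotype, and the interaction at 6 h and at 48 h. The p values were adjusted by Benjamini-Hochberg over all genes in each contrast and called under 0.05. Where no sample of a group was well above background for a gene, the fold is a bound: the mean of the other group against, in each dim sample, the lowest value well above background on that array or the gene's own value if higher. Replicate numbers were not taken to join samples across genotypes in the main fit, since the labels do not say that they do. Same-numbered residuals all correlated positively (0.092 to 0.534) and best with each other, but such samples also share slide and dye. Among samples of equal slide and dye, same-numbered ones still correlated higher, at 0.169 and 0.267 against 0.116 and -0.009 at 0 h. At 6 h the values were 0.092 and 0.1 against -0.06 and 0.021, and at 48 h 0.132 and 0.179 against 0.06 and 0.114. Shared slide and dye alone therefore do not give this order. The replicate as a block is therefore given as an alternative.

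Gene lists were 25 sets holding 426 loci, fixed before the data were examined, as were the samples' groups, the tests, the thresholds and the alternatives other than those named as later. They covered pattern-triggered immunity, camalexin, indole and aliphatic glucosinolates, genes induced by jasmonate and ethylene together, jasmonate synthesis and signalling, ethylene, salicylate, abscisic acid and dehydration, resistance to Botrytis, glutathione and detoxification, flavonoids, phenylpropanoids and lignin, photosynthesis, the circadian clock, heat shock, senescence, auxin response, cell cycle, leaf polarity and meristem, stomatal lineage, trichome, root, vascular tissue, and Elongator with tRNA modification. The stomatal, trichome, root and vascular lists stand for other cell types in a leaf sample. WRKY70 and BCAT4 were dropped for lack of a usable probe; ASB1, TT8, MYB12, KNAT1, KNAT2, KNAT6, STM, CYCB1;1, CYCB2;1, HSP22, MUTE, SPCH, EPF2, GL1, GL3, TTG2, COBL9, WER, PLT1 and PLT2 did not pass the filters. Lists were tested with cameraPR (preset correlation 0.01) against all other genes, adjusted over the 25 lists of a contrast, and again with an estimated correlation and with fry, which tests whether a list moves one way on balance and does not compare it with other genes. Within a list, p values were also adjusted over its members.

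Genes were named by a rule. DRL1 was named in every sample. For the genotype contrasts and the wild type time contrasts the 8 largest rises and 8 largest falls were named among called genes with a symbol that is not a locus code. These also had to be well above background in at least 2 of 3 samples of a group and, between genotypes, to have the same direction in all 3 same-numbered comparisons or, between times, no overlap of the groups. For the interactions the 5 largest in each direction were named. From each list described up to 4 called members with the largest difference were taken, or values of up to 2 bright members where none was called. PDF1.2A, ORA59, ERF1, PAD3, WRKY33, PR1, VSP2 and LHCB1.1 were taken in any contrast. For drl1 over time the genes of the wild type were named.

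Correlations of genotype differences between times are Pearson and Spearman values across genes, with a jackknife over the samples. The spread ratio of the responses is the standard deviation over genes of the drl1 change divided by that of the wild type change. Principal components were taken over the 16587 genes without missing values, centred per gene.

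The alternatives were no array effect, processed signals scaled to their 75th percentile, quantile normalization replaced by the 75th percentile, no dye term, Cy5 samples alone, no filter on dim probes, a filter at 9 of 18 samples, an offset of 16, the replicate as a block, leaving out each replicate in turn with the array correlation held, the mean of a gene's probes, only the groups of the comparison, slide as a fixed term (genotype and interaction) or a random one (time), a minimum of 2-fold, and the authors' table. In the genotype and interaction contrasts, slide as a fixed term and the replicate as a block were fitted without the array effect. Over time, slide as a random term took the place of the array effect. Chosen after seeing the data were keeping the spots marked as outliers, requiring at least 2 values per group, and the alternatives for the spread ratios. Because a single value can stand for a group, the first of these also checks named genes such as PAD3, which differed by -1.50 at 6 h and 3.17 at 48 h with those spots kept.

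The model fit and the list test were tried on simulated log2 values with the real design, with changes added to a small share of known genes. The values were drawn as already normalized, independent between genes and without a dye or slide effect. Background correction, scaling, correlation between genes and changes as widespread as in the data were therefore not tested. Of genes changed by 1 on the log2 scale 95.5% to 100% were called in the genotype and wild type time contrasts, of those changed by 0.5 49.3% to 62.7%, and in the interactions at 6 h and 48 h 92.5% and 83.6% of those changed by 1 and 13.4% and 29.9% of those changed by 0.5. Unchanged genes made up 2.3% to 9.1% of the calls. The drl1 time contrasts were not simulated. A list of 36 genes shifted by 0.4 was called in each of the 7 others, with at most 2 of 24 other lists. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.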

Results

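Transcript levels were measured in rosette leaves of Arabidopsis thaliana, in Columbia wild type plants and in the mutant drl1, at 0, 6 and 48 h after inoculation with the grey mould fungus Botrytis cinerea, strain B05. Spore drops were set on leaves lightly wounded with a needle. DRL1 (Deformed Roots and Leaves 1, AT1G13870) encodes a protein that works with Elongator, a complex of the RNA polymerase II elongation machinery that also acts in tRNA modification. The 18 samples fell into 6 groups of 3, and each replicate was an independent experiment with other plants. No sample was mock-inoculated, so differences against 0 h hold the effects of infection, wounding and time together.

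Each sample was one colour channel of an Agilent 2-colour array, and the 18 channels came from 14 arrays on 4 slides. Between 54.7% and 68.4% of the spots were well above background per sample, with a median of 65.5%, and the correlation between replicates across genes was 0.985 to 0.998. The number of arrays limits the precision. Values are log2 intensities and differences are on the log2 scale, drl1 minus wild type or later time minus 0 h. A value after ± is the standard error (SE) of a difference unless marked SD, and n = 3 per group unless given. After outlier spots were left out, 1306 of the 20369 genes tested had a single value in at least 1 group, and n is given where a compared group of a named gene held fewer than 3. A gene is said to have changed where its limma adjusted p was under 0.05. Each gene is given by its brightest probe, and other probes of a gene could show a smaller difference. Genes given as furthest or largest between genotypes or over time in wild type had a symbol, were well above background in at least 2 of 3 samples of a group, and differed the same way in all 3 same-numbered comparisons or, over time, without overlap of the groups. A list adjusted p is from limma's camera test of the list against all other genes at a preset correlation, and the list calls given here held with an estimated correlation.

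DRL1 itself was lower in the mutant at each time. Its level was 9.61 ± 0.08 (SD) in wild type and 6.99 ± 0.11 in drl1 at 0 h, 9.53 ± 0.32 and 7.38 ± 0.07 at 6 h, and 9.57 ± 0.05 and 7.26 ± 0.02 at 48 h. The differences were -2.62 ± 0.12, -2.17 ± 0.11 and -2.22 ± 0.12 (adjusted p 9.69e-12, 2.06e-11 and 2.89e-11), and with the scanner software's processed signals -4.49, -3.36 and -3.43. All 9 drl1 samples lay between 6.89 and 7.45 and all 9 wild type samples between 9.16 and 9.72, so each sample matched its genotype label. The residual signal was above background in all 18 samples, and 1 probe read the gene, at chromosome 1, 4747460 to 4747519, in the build named by the array design. Where that probe lies relative to the mutation is not known from the labels.

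**Figure D1:**
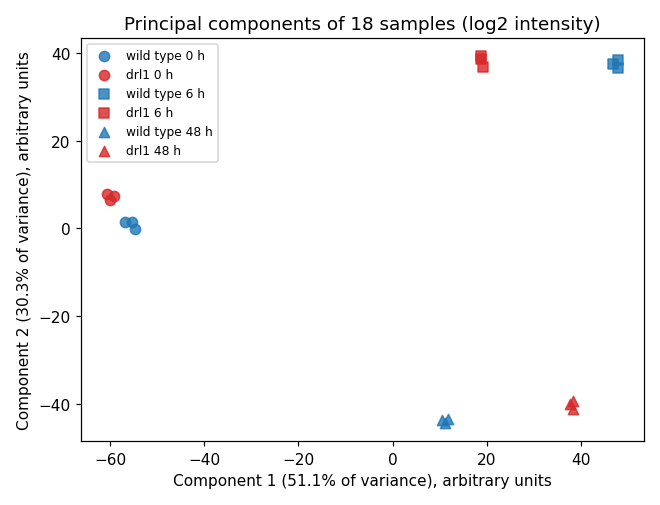
Principal components 1 and 2 (51.1% and 30.3% of the variance) of the 18 samples over the 16587 genes with a value in every sample, with wild type in blue, drl1 in red, circles for 0 h, squares for 6 h and triangles for 48 h. On component 1 the 0 h samples lie between -60.8 and -54.8, and drl1 lies below wild type at 6 h (18.8 to 19.3 against 46.9 to 47.9) and above it at 48 h (37.7 to 38.4 against 10.6 to 11.8).

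The first comparison asked how drl1 leaves differed from wild type at 0 h. Several groups of induced defence genes were lower in the mutant. Of 36 measured genes of pattern-triggered immunity, the response to microbial molecules at the cell surface, 21 fell and 2 rose (27 and 2 adjusted over the list alone), with a median difference of -0.36 and a list adjusted p of 1.1e-10. WRKY53, a transcription factor gene, differed by -1.50 ± 0.09, SYP122, a membrane fusion gene, by -1.50 ± 0.12, and WRKY18 by -1.61 ± 0.18 (n = 1 in wild type and 2 in drl1). Of 10 genes of indole glucosinolate metabolism 8 fell and none rose (8 fell and 1 rose adjusted over the list alone; median -0.71, list adjusted p 2.28e-07). They included the P450 gene CYP81F2 at -2.30 ± 0.17, the methyltransferase genes IGMT1 at -2.18 ± 0.11 and IGMT2 at -1.66 ± 0.12, which are near-identical, and the transporter gene PEN3 at -1.20 ± 0.19. Of 16 camalexin genes, whose products make the main Arabidopsis phytoalexin, 7 fell (7 adjusted over the list alone; list adjusted p 1.29e-05). Among these were GSTF6 at -2.08 ± 0.12, PAD3, the last enzyme of the pathway, at -1.29 ± 0.13, and the regulator WRKY33 at -1.10 ± 0.13. In the set of genes induced by jasmonate and ethylene together, 5 of 16 fell and 1 rose (7 and 1 adjusted over the list alone; list adjusted p 0.000292). The regulator ORA59 differed by -1.86 ± 0.12 and PR4 by -1.09 ± 0.24. The salicylate defence list was not called, with 2 of 19 up and 5 down (2 and 5 adjusted over the list alone; median 0.02, list adjusted p 0.507).

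The single genes furthest below wild type at 0 h, after DRL1, were the blue copper protein gene BCB at -2.39 ± 0.16, CYP81F2, the phloem lectin gene PP2-A5 at -2.18 ± 0.11, IGMT1, PCR2 at -2.13 ± 0.12, GSTF6 and the thionin gene THI2.2 at -2.03 ± 0.12. Those furthest above were CHS (chalcone synthase, the first enzyme of flavonoid synthesis) at 2.47 ± 0.32, the asparagine synthetase gene ASN1 at 2.37 ± 0.10, AGL19 at 2.3 ± 0.10, the early light-induced gene ELIP1 at 2.26 ± 0.13, KCS8 at 1.95 ± 0.13, CER4 at 1.80 ± 0.10, the retroelement SADHU3-2 at 1.72 ± 0.14 and ESE3 at 1.68 ± 0.10. Of 16 flavonoid genes 5 rose and none fell (6 adjusted over the list alone; list adjusted p 0.000161). CHIL differed by 1.15 ± 0.09 and FLS1 by 1.08 ± 0.09, and DFR was at least 2.53-fold higher. Of 20 cell cycle genes 8 rose and none fell (11 adjusted over the list alone; list adjusted p 9.89e-07). TSO2 differed by 0.97 ± 0.13 (n = 2 in drl1), MCM2 by 0.79 ± 0.10 and CYCD3;3 by 0.72 ± 0.10. Of 12 auxin response genes 7 rose (7 up and 2 down adjusted over the list alone; list adjusted p 0.00724). IAA5 was 2.04-fold higher in drl1. PDF1.2A, the plant defensin gene of the jasmonate and ethylene response, stood at 8.35 ± 0.28 (SD) in wild type and 7.54 ± 0.13 in drl1 (-0.82, adjusted p 0.23), ERF1 differed by -0.06 (adjusted p 0.765), PR1, a salicylate marker, by 0.06 and LHCB1.1 by 0.02. The storage protein gene VSP2, a marker of the wound branch of jasmonate signalling, was higher in drl1 by 1.01.

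At 0 h 3773 genes changed, 1772 up and 2001 down, and 326 of them by at least 2-fold (87 up and 239 down). With slide as a term in the model and no array effect 4387 changed, against 4255 with the array effect alone left out. Within slides the genotype difference correlated at 0.824 across genes between the slide of replicate 1 and that of replicates 2 and 3. Under scaling to the 75th percentile in place of quantile normalization 996 genes changed, the median of all genes was -0.217, and relative to it the medians of the cell cycle and flavonoid lists became negative (-0.204 and -0.099, list adjusted p 0.448 and 0.871; over all alternatives of that test from 1.95e-07 and 4.15e-05). That scaling also ended the calls of CER4, SADHU3-2, CHIL, FLS1, DFR, MCM2 and PR4 (adjusted p 0.0662 to 0.691), and averaging the probes of a gene ended that of TSO2; other alternatives kept these calls, apart from a minimum of 2-fold.

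At 6 h the comparison asked how the genotypes differed early after inoculation. All 16 camalexin genes were lower in drl1 (16 adjusted over the list alone), with a median difference of -1.36 and a list adjusted p of 4.17e-12. TSA1 and CYP79B2, which act on the route from tryptophan synthesis to indole compounds, differed by -1.85 ± 0.13 and -1.77 ± 0.14 (n = 3 and 2), and PAD3 by -1.62 ± 0.21 (16.03 ± 0.03, SD, in wild type and 14.61 in the 1 drl1 sample with a value). Of the 36 pattern-triggered immunity genes 29 fell and 1 rose (29 and 1 adjusted over the list alone; median -0.71, list adjusted p 4.55e-13). The transcription factor genes ZAT10 and WRKY40 differed by -1.94 ± 0.09 and -1.58 ± 0.15, and the danger peptide gene PROPEP3 by -1.81 ± 0.10. In the jasmonate and ethylene set 11 of 16 fell and 1 rose (11 and 1 adjusted over the list alone; median -1.08, list adjusted p 3.92e-06). ERF5 differed by -1.93 ± 0.09, ERF6 by -1.70 ± 0.11, PR4 by -1.47 ± 0.23, ERF1 by -1.34 ± 0.09 and ORA59 by -1.08 ± 0.11, while PDF1.2A stood at 12.07 ± 0.40 (SD) in wild type and 11.33 ± 1.51 in drl1 (adjusted p 0.338). Glutathione and detoxification genes fell in 21 of 25 cases (22 adjusted over the list alone; median -0.77, list adjusted p 1.43e-09), and indole glucosinolate genes in 7 of 10 with 1 up (9 and 1 adjusted over the list alone; list adjusted p 0.00115). The sulfotransferase gene SOT16 differed by -1.61 ± 0.12 (n = 3 and 2). Of 19 salicylate defence genes 9 fell and none rose (9 adjusted over the list alone; list adjusted p 0.000164). NIMIN1 differed by -1.40 ± 0.16 and WRKY54 by -1.29 ± 0.10. Senescence genes fell in 10 of 18 cases and rose in 1 (12 and 1 adjusted over the list alone; list adjusted p 0.000589). NAP differed by -1.24 ± 0.16.

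In the opposite direction, 27 of 44 photosynthesis genes were higher in drl1 at 6 h and none lower (31 adjusted over the list alone; median 0.56, list adjusted p 1.82e-10). The light-harvesting gene LHCB3 stood at 13.52 ± 0.54 (SD) in wild type and 15.81 ± 0.25 in drl1, a difference of 2.27 ± 0.17, and LHCA4 and LHCB4.2 differed by 1.43 ± 0.13 and 1.2 ± 0.14. Aliphatic glucosinolate genes rose in 12 of 17 cases and fell in 2 (12 and 2 adjusted over the list alone; median 0.61, list adjusted p 0.00102). CYP83A1 differed by 1.12 ± 0.14 and MAM3 by -1.20 ± 0.07. Auxin response genes rose in 8 of 12 cases (9 adjusted over the list alone; list adjusted p 3.86e-05) and leaf polarity genes in 9 of 13 (9 adjusted over the list alone; list adjusted p 0.000875). YAB5 differed by 1.52 ± 0.09. The single genes furthest above wild type were VSP2 at 3.38 ± 0.14 and its neighbour VSP1 at 2.90 ± 0.22, then AGL19 at 2.37 ± 0.10, SADHU3-2, at least 4.73-fold higher, LHCB3, DRT100 at 1.96 ± 0.17, MBP2 at 1.91 ± 0.09 and GASA6 at 1.87 ± 0.15. Those furthest below were the mitochondrial carrier gene DIC2 at -2.47 ± 0.15, PCR1 at -2.23 ± 0.09, DRL1, BAP1 at -2.09 ± 0.17, NIMIN-2 at -2.01 ± 0.11, ZAT10, ERF5 and ERF-1 at -1.87 ± 0.20. By group means, the probe with the smallest difference gave 0.419 for VSP1, 0.64 for MBP2 and 3.332 for VSP2.

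At 6 h 7696 genes changed, 3611 up and 4085 down, and 627 by at least 2-fold (268 up and 359 down). With slide as a term and no array effect 8056 changed, against 7793 with the array effect alone left out. The genotype difference correlated at 0.853 across genes between the 2 slides. A fit to the 6 h groups alone called 4021 genes and scaling to the 75th percentile 2823, and that scaling ended the call of PAD3 (-1.31, adjusted p 0.106, over all alternatives from 7.4e-09).

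By 48 h the camalexin, detoxification and senescence genes ran the other way, and 573 of the 695 genes that changed by at least 2-fold (82.4%) were higher in drl1. Of 25 glutathione and detoxification genes 22 rose and none fell (25 adjusted over the list alone; median 1.37, list adjusted p 1.06e-22). GSTU11 differed by 2.76 ± 0.16, UGT74E2 by 2.67 ± 0.19 and GSTU12 by 3.83 ± 0.17 (n = 1 in drl1). Camalexin genes rose in 14 of 16 cases (14 adjusted over the list alone; median 1.00, list adjusted p 1.54e-11). PAD3 stood at 10.88 ± 0.42 (SD, n = 2) in wild type and 14.22 (n = 1) in drl1, a difference of 3.16 ± 0.22, and the P450 genes CYP71A13 and CYP71A12 differed by 2.62 ± 0.11 and 1.81 ± 0.13. Of 26 jasmonate synthesis and signalling genes 17 rose and none fell (18 adjusted over the list alone; median 0.95, list adjusted p 3.31e-10). VSP1 differed by 3.44 ± 0.24 (n = 2 in drl1), VSP2 by 2.95 ± 0.15 and the repressor gene JAZ10 by 2.04 ± 0.12. Flavonoid genes rose in 12 of 16 cases (12 adjusted over the list alone; list adjusted p 2.46e-08). The anthocyanin regulator PAP1 differed by 2.31 ± 0.15. Phenylpropanoid and lignin genes rose in 11 of 19 cases and fell in 1 (11 and 1 adjusted over the list alone; list adjusted p 0.000141). CAD8, an alcohol dehydrogenase gene of that list, differed by 2.76 ± 0.11. Senescence genes rose in 12 of 18 and fell in 2 (13 and 2 adjusted over the list alone; list adjusted p 1.37e-05). SAG29 differed by 2.79 ± 0.12. In the list of genes known for resistance to Botrytis 6 of 16 rose and 2 fell (6 and 2 adjusted over the list alone; list adjusted p 0.00464). The MYB gene BOS1 differed by 2.32 ± 0.12. Aliphatic glucosinolate genes, higher in drl1 at 6 h, were lower at 48 h (list adjusted p 0.0277).

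The genes of the jasmonate and ethylene set were not shifted together at 48 h: 4 of 16 rose and 3 fell (4 and 3 adjusted over the list alone, median -0.10, mean 0.03, list adjusted p 0.735). PDF1.2A was 18.171 in replicate 2 of both genotypes. Quantile normalization gives such bright spots of equal rank the same value, so a difference can be hidden there. PDF1.2A stood at 17.84 ± 0.30 (SD) in wild type and 17.998 ± 0.176 in drl1 (fitted difference -0.53, adjusted p 0.435, and 0.157 as in the means without the array effect, adjusted p 0.812), ERF1 was higher by 1.5 ± 0.17 (n = 2 and 1), and WRKY33 differed by -0.09 (adjusted p 0.821; n = 1 and 1). Of the 36 pattern-triggered immunity genes 14 rose and 8 fell (14 and 10 adjusted over the list alone; list adjusted p 0.115). PROPEP3 differed by 2.99 ± 0.11 and WRKY53 by -1.35 ± 0.10. PR1 was higher in drl1 by 0.87 (adjusted p 0.000839) and PR2, another pathogenesis-related gene, lower by -1.53 ± 0.43 (adjusted p 0.0116), within a salicylate list of which 5 of 19 rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p 0.128). Among genes with the same direction in all 3 same-numbered comparisons, for which GSTU12, VSP1 and PAD3 lacked values, the furthest above wild type were the glucosidase gene BGLU27 at 3.98 ± 0.10, the methyl salicylate and methyl benzoate synthesis gene BSMT1, at least 13.7-fold higher, the terpene synthase gene TPS04 at 3.36 ± 0.09, the lipoxygenase gene LOX1 at 3.23 ± 0.14, PROPEP3, VSP2, GPT2 at 2.94 ± 0.21 and MSRB9 at 2.91 ± 0.11. Those furthest below were BGAL1 at -2.38 ± 0.14, DRL1, LTL1 at -2.15 ± 0.11, BT2 at -2.04 ± 0.11, PCR1 at -1.97 ± 0.10, BT5 at -1.80 ± 0.10, SIS at -1.64 ± 0.16 and PR2.

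At 48 h 5522 genes changed, 2900 up and 2622 down. With slide as a term and no array effect 6382 did, against 6284 with the array effect alone left out. All 48 h samples were on 1 slide, so no second slide gave a value. Replicates 1 and 3 of each genotype at 48 h were the 2 channels of 1 array, so without replicate 2 a group rested on 1 array. The count was 2801 without wild type replicate 2, 2948 without drl1 replicate 2, 3623 in Cy5 samples alone and 2154 under scaling to the 75th percentile. That scaling ended the calls of ERF1 and PR1, and leaving out either sample ended that of PR2; over all alternatives their adjusted p ranged from 1.15e-10 to 0.177, from 2.63e-05 to 0.203 and from 1.38e-07 to 0.118.

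**Figure D2:**
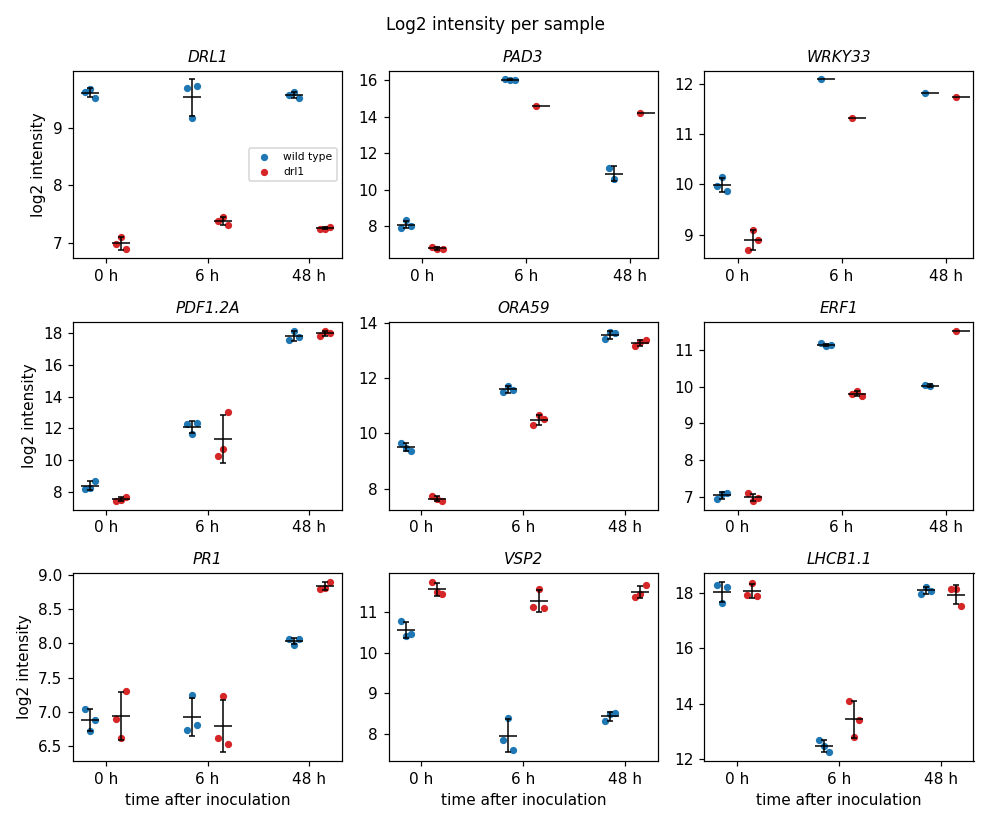
Log2 intensity of 9 genes by genotype (wild type blue, drl1 red) and time; each point is a sample, the black bar is the mean ± SD, and PAD3, WRKY33 and ERF1 have fewer points where an outlier spot was left out. DRL1 is lower in drl1 at each time, PAD3 is lower in drl1 at 0 h and 6 h and higher at 48 h, and VSP2 stays near 11.3 to 11.6 in drl1 while it stands at 7.94 and 8.43 in wild type at 6 h and 48 h.

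**Figure D3:**
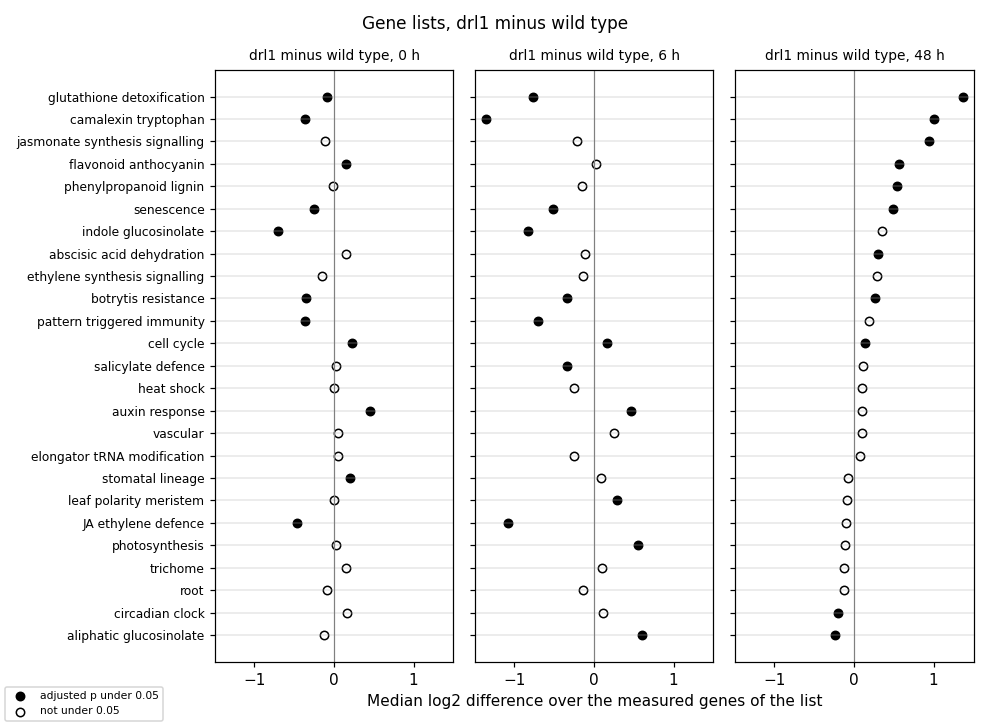
Median log2 difference, drl1 minus wild type, of each of 25 gene lists at 0, 6 and 48 h; filled points mark a list adjusted p under 0.05. The camalexin median goes from -1.36 at 6 h to 1.00 at 48 h, and at 0 h the medians of the cell cycle, flavonoid and stomatal lists turn negative relative to all genes under scaling to the 75th percentile.

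Across the 3 times, genotype differences at 0 h and 6 h tended to share their direction. Of 2272 genes changed at both times 1962 did so (864 up and 1098 down, against 314.1 and 401.3 for independent calls), and the correlation across genes was 0.434 (Spearman 0.365, jackknife SE 0.026). Between 6 h and 48 h it was -0.214 (Spearman -0.232, SE 0.039; -0.086 with processed signals), and of 2913 genes changed at both times 853 kept their direction, 1255 were lower at 6 h and higher at 48 h, and 805 the reverse. Among the 116 that changed by at least 2-fold at both, 81 went from lower to higher and 4 from higher to lower. Between 0 h and 48 h the correlation was 0.091 (Spearman 0.158, SE 0.020) and became -0.257 under scaling to the 75th percentile. The 3 correlations are across genes, which are not independent replicates, and these times share no sample. The 6 h and 48 h groups do share arrays, replicate 3 at 6 h with replicate 2 at 48 h in each genotype. The fit joins them through the array effect and the dye term, so their genotype differences are not independent estimates.

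In wild type, 6 h against 0 h asked what changed in leaves early after inoculation. Detoxification genes rose in 25 of 25 cases (25 adjusted over the list alone), with a median of 4.01 and a list adjusted p of 1.73e-19, and the glutathione transferase genes GSTU24 and GSTU4 rose by 7.95 ± 0.12 and 6.45 ± 0.16 and GSTU25 by at least 108-fold. Camalexin genes rose in 15 of 16 cases and fell in 1 (15 and 1 adjusted over the list alone; median 2.80, list adjusted p 4.79e-10). PAD3 rose by 7.89 ± 0.14 (8.09 ± 0.20 to 16.03 ± 0.03, SD) and CYP71A13 by 5.35 ± 0.10. Of 16 genes of the jasmonate and ethylene set 14 rose (14 adjusted over the list alone; median 2.77, list adjusted p 4.16e-08). PR4 rose by 4.13 ± 0.24, ERF1 by 4.11 ± 0.10 and PDF1.2A by 3.54 ± 0.44. Pattern-triggered immunity genes rose in 25 of 36 cases and fell in 1 (25 and 1 adjusted over the list alone; list adjusted p 4.16e-08). NHL10 rose by 5.43 ± 0.10 and WRKY40 by 4.98 ± 0.16. Photosynthesis genes fell in 36 of 44 cases and rose in 1 (36 and 1 adjusted over the list alone; median -0.91, list adjusted p 8.02e-08), and aliphatic glucosinolate genes fell in 15 of 17 (15 down and 1 up adjusted over the list alone; list adjusted p 0.00011). Their regulator MYB29 changed by -2.22 ± 0.09. The largest single rises also included the transporter gene ABCG40 at 6.99 ± 0.14 (n = 1 at 6 h), DIN11 at 6.57 ± 0.14 and the glycosyltransferase genes UGT74E2 at 6.26 ± 0.20 (n = 2 at 6 h) and UGT76B1 at 6.13 ± 0.19. The largest falls were LHCB2.3 at -6.65 ± 0.20, LHCB1.1 at -5.65 ± 0.29, COL2 at -5.20 ± 0.10, LHCB2.1 at -4.55 ± 0.14, LHCB2.2 at -4.40 ± 0.24, THI2.2 at -4.25 ± 0.11, the clock gene CCA1 at -4.10 ± 0.14 and CAD9 at -4.06 ± 0.16 (n = 2 at 0 h). The LHCB1 and LHCB2 genes are near-identical within each family, so a probe for one can read another. By group means, the probe with the smallest difference gave 1.612 for UGT76B1, -0.791 for CCA1 and -5.901 for LHCB2.3. VSP2 fell by 2.54 on the log2 scale.

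At 48 h against 0 h in wild type, the plant defensin genes PDF1.2B, PDF1.2C, PDF1.3 and PDF1.2A, a near-identical family, had the largest rises, at 10.63 ± 0.17, 10.61 ± 0.40, 10.38 ± 0.27 and 9.51 ± 0.45. Next came the acetyltransferase gene NATA1 at 7.58 ± 0.14, DIN11 at 7.11 ± 0.14 and the extensin genes EXT3 at 6.77 ± 0.11 and EXT4 at 6.52 ± 0.15 (n = 1 at 48 h). Of 16 genes of the jasmonate and ethylene set 15 rose (15 adjusted over the list alone; median 3.56, list adjusted p 1.23e-17). ORA59 rose by 4.12 ± 0.12 and ERF1 by 3.00 ± 0.13 (n = 2 at 48 h). Detoxification genes rose in 21 of 25 cases and fell in 2 (21 and 2 adjusted over the list alone; list adjusted p 1.07e-11), camalexin genes in 14 of 16 with 1 down (15 and 1 adjusted over the list alone; list adjusted p 1.83e-09). PAD3 rose by 2.71 ± 0.14 (n = 2 at 48 h). Senescence genes rose in 14 of 18 cases (14 adjusted over the list alone; list adjusted p 1.86e-09). SAG13 rose by 5.56 ± 0.12 and SAG12 by 4.14 ± 0.09. Auxin response genes fell in 9 of 12 cases and rose in 2 (9 and 2 adjusted over the list alone; list adjusted p 0.00843). Among markers of other cell types, stomatal lineage genes fell in 7 of 7 cases (7 adjusted over the list alone; list adjusted p 0.00843) and vascular genes in 7 of 10 (8 adjusted over the list alone; list adjusted p 0.00217). MYB60 changed by -0.89 ± 0.09 and XCP2, a xylem protease gene, by -1.66 ± 0.18. Photosynthesis genes fell in 15 of 44 cases (11 adjusted over the list alone, median -0.26, list adjusted p 0.0575, and adjusted p = 0.049 with an estimated correlation), and LHCB1.1 stood at 18.09 against 18.04 at 0 h. LHCB1.1 was 18.218 in replicate 3 at 0 h and in replicate 2 at 48 h, a tie of rank that can hide a difference. The largest falls were the cold-induced genes KIN2 at -4.80 ± 0.23 (n = 1 at 0 h) and KIN1 at -4.08 ± 0.20, THI2.2, at least 23.7-fold lower, PP2-A5 at -4.46 ± 0.11, the wax genes CER1 at -4.26 ± 0.22 and LACS1 at -4.20 ± 0.15, the expansin gene EXPA5 at -4.16 ± 0.09 and LHCB2.3 at -4.06 ± 0.20. Other probes of some of these genes gave much smaller differences of the same sign. By group means, the smallest were 1.578 for EXT3, 1.96 for EXT4, -0.392 for CER1, -0.653 for LACS1 and -1.474 for EXPA5. PR1 rose by 1.18.

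In wild type 12991 genes changed at 6 h (5821 up and 7170 down) and 9798 at 48 h (4367 up and 5431 down), and 3971 and 2193 did so by at least 2-fold. Every slide held either 0 h samples or later ones, so slide and time cannot be told apart in these comparisons, and with slide as a random term 13020 and 10058 changed. Scaling to the 75th percentile gave 8078 and 6380.

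The same comparisons in drl1 asked whether the mutant responded like the wild type. At 6 h in drl1, PAD3 rose by 7.57 ± 0.21 (n = 1 at 6 h), GSTU24 by 7.68 ± 0.12, UGT74E2 by 8.04 ± 0.20 (n = 2 at 6 h), NHL10 by at least 29-fold, PDF1.2A by 3.83 ± 0.44 and ERF1 by 2.83, and LHCB2.3 and LHCB1.1 differed by -6.00 ± 0.20 and -4.70 ± 0.29. Detoxification genes rose in 24 of 25 cases (24 adjusted over the list alone; list adjusted p 1.4e-24) and photosynthesis genes fell in 20 of 44 and rose in 1 (20 and 1 adjusted over the list alone; median -0.39, list adjusted p 0.000504). At 48 h in drl1, PDF1.2C, PDF1.2B and PDF1.2A rose by 10.83 ± 0.40, 10.74 ± 0.17 and 9.80 ± 0.45, ORA59 by 5.64 ± 0.12, PAD3 by 7.17 (n = 1 at 48 h), CYP71A13 by at least 71.7-fold and SAG13 by 8.12 (n = 1 at 48 h). The fitted rise of PDF1.2A lies below the difference of its group means. VSP2 differed by -0.03 (adjusted p 0.866), but rose by 0.42 with processed signals (adjusted p 0.000537). Jasmonate synthesis and signalling genes rose in 15 of 26 cases and fell in 3 (15 and 3 adjusted over the list alone; median 0.86, list adjusted p 0.000212). JAZ8 rose by 3.87 ± 0.11.

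In drl1 10525 genes changed at 6 h and 11917 at 48 h, and with slide as a random term 10471 and 12039 did. Scaling to the 75th percentile gave 5212 and 6686. Of 9149 genes changed in both genotypes at 6 h 9047 did so in the same direction, and at 48 h 7632 of 7937. The spread of the drl1 response across genes was 0.795 times that of the wild type at 6 h (jackknife SE 0.011) and 1.289 times at 48 h (SE 0.019).

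**Figure D4:**
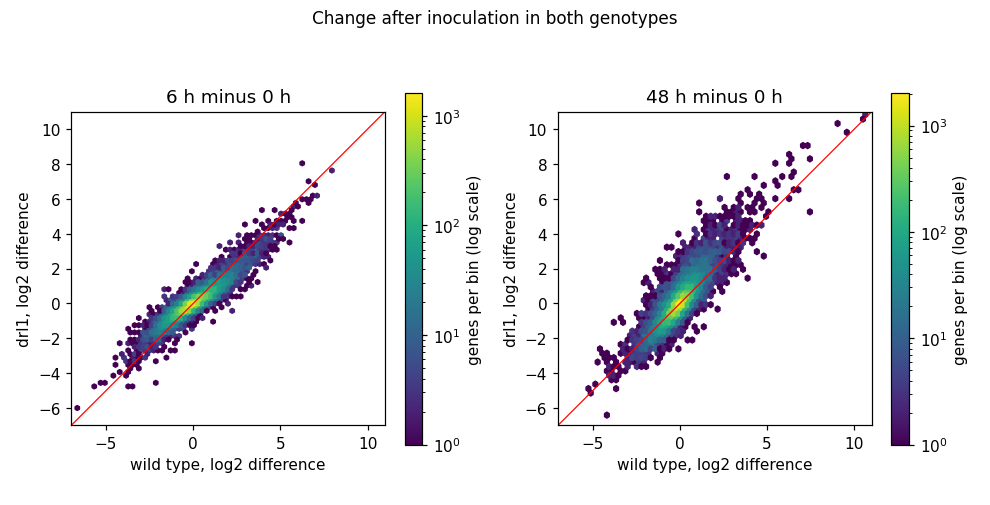
Log2 change against 0 h in drl1 (vertical) and wild type (horizontal) for 20369 genes at 6 h and 48 h, shaded by the number of genes, with the red line marking equal change. The correlation across genes is 0.917 with a slope of 0.729 at 6 h, and 0.848 with a slope of 1.093 at 48 h.

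The interaction of genotype and time tested whether the change from 0 h differed between the genotypes. At 6 h photosynthesis genes fell less in drl1 (18 of 44 had a positive interaction and none a negative one, 19 adjusted over the list alone; median 0.57, list adjusted p 5.36e-09). LHCB3 had an interaction of 2.21 ± 0.26. Camalexin genes rose less, with 11 of 16 negative and 1 positive (11 and 1 adjusted over the list alone; median -0.69, list adjusted p 1.45e-05). TSA1 had an interaction of -1.69 ± 0.20. That of PAD3 was -0.32 (adjusted p 0.423; n = 1 in drl1 at 6 h) and became 2.12 with processed signals. Aliphatic glucosinolate genes had 9 of 17 positive interactions (10 adjusted over the list alone; list adjusted p 1.45e-05). VSP2 at 2.37 ± 0.20, JAL23 at 2.3 ± 0.17, the nitrate transporter gene NRT1.1 at 2.19 ± 0.21 (n = 2 in wild type and 1 in drl1 at 6 h) and MLP28 at 2.15 ± 0.30 (n = 2 in wild type at 0 h) were the other largest positive values. NIMIN1 at -2.67 ± 0.24, BCAT-2 at -2.36 ± 0.19, BAP1 at -2.33 ± 0.25, CHS at -2.28 ± 0.44 and NIMIN-2 at -2.18 ± 0.17 were the largest negative ones. The other probe of JAL23 gave an interaction of 0.141 by group means.

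At 48 h the change from 0 h lay higher in drl1 than in wild type for most defence groups. This interaction also holds the genotype difference at 0 h. Pattern-triggered immunity and indole glucosinolate genes were lower in drl1 at 0 h (list adjusted p 1.1e-10 and 2.28e-07). Neither list was called between genotypes at 48 h (list adjusted p 0.115 and 0.0575, the latter 0.0447 with an estimated correlation). ORA59 was still lower in drl1 at 48 h (13.169 to 13.378 against 13.414 to 13.675). Detoxification genes had positive interactions in 24 of 25 cases (24 adjusted over the list alone; median 1.95, list adjusted p 9.97e-26), camalexin genes in 15 of 16 (16 adjusted over the list alone; median 1.31, list adjusted p 6.35e-16), jasmonate genes in 19 of 26 with 1 negative (20 and 2 adjusted over the list alone; list adjusted p 1.13e-11), pattern-triggered immunity genes in 20 of 36 with 1 negative (23 and 1 adjusted over the list alone; list adjusted p 2e-09) and indole glucosinolate genes in 7 of 10 (9 adjusted over the list alone; list adjusted p 1.25e-07). UGT74E2 at 4.49 ± 0.26, PAD3 at 4.45 ± 0.25 (n = 2 and 1 at 48 h), MSRB9 at 4.03 ± 0.17 (n = 2 in wild type at 0 h), BGLU27 at 4.02 ± 0.14 and TPS04 at 3.85 ± 0.13 were the largest positive values. ERF1 stood at 1.55 (n = 2 and 1 at 48 h), ORA59 at 1.52 and VSP2 at 1.94. VSP2 fell in wild type (-1.975) and was not called in drl1, but rose there by 0.424 with processed signals. ASN1 at -2.74 ± 0.14, BT2 at -2.41 ± 0.15, TCH4 at -2.40 ± 0.22 (n = 2 in drl1 at 0 h), LTL1 at -2.23 ± 0.15 and CER1 at -2.15 ± 0.33 (n = 2 in drl1 at 0 h) were the largest negative ones.

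The interaction was past the threshold for 3696 genes at 6 h (1715 positive and 1981 negative) and 4183 at 48 h (2423 and 1760). With slide as a term and no array effect it was so for 4203 and 4949. Scaling to the 75th percentile gave 410 and 1744 and ended the calls of BAP1, CHS, NIMIN1, LTL1 and, at 48 h, ERF1 (adjusted p 0.0642 to 0.175), averaging the probes of a gene ended that of CER1, and the count at 48 h was 2748 without wild type replicate 2.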

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

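All tests that weigh the 3 patterns here, except the clock correlation at 0 h, and all counts of other splits were chosen after the results were seen.

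The change over time differed between the genotypes, by the interaction test, for 3696 genes at 6 h and 4183 at 48 h. Other splits of the 12 samples exchanged genotypes within each time. Among 100 drawn for each, 2 gave at least as many genes as the real one at 6 h, the real split included, with 3746 in the other, and 1 did at 48 h (highest other 2338). The split with 3746 kept the 6 h genotypes apart and mixed the 0 h samples, and the highest other at 48 h kept the 48 h genotypes apart, so these counts also hold the main effect of genotype and do not test the interaction. After the genotype effect common to both times was removed, 1 of the 100 splits, the real one, reached the real count at 6 h (3693, highest other 448) and at 48 h (4186, highest other 1599), so both shares are under 0.05. That effect was estimated with the real genotype labels, which left the real counts nearly unchanged and lowered the highest other ones. The removal thus favours the real split, and these shares do not exclude chance. In the simpler comparisons 10 splits exist, too few for a share under 0.05, and 1 split, the real one, reached the real count in each. Every other split mixes the groups compared, so a real difference widens the spread within its groups and lowers its count. These low counts therefore do not test chance. The real counts and the highest others were 3773 and 3 (genotypes at 0 h), 7696 and 4 (6 h), 5522 and 42 (48 h), 12991 and 9 (wild type 6 h), 9798 and 37 (wild type 48 h), 10525 and 39 (drl1 6 h) and 11917 and 48 (drl1 48 h).

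At 6 h the named genes with an interaction were VSP2 (2.37), JAL23 (2.3), LHCB3 (2.21), NRT1.1 (2.19) and MLP28 (2.15) above, and NIMIN1 (-2.67), BCAT-2 (-2.36), BAP1 (-2.33), CHS (-2.28) and NIMIN-2 (-2.18) below. At 48 h they were UGT74E2 (4.49), PAD3 (4.45), MSRB9 (4.03), BGLU27 (4.02) and TPS04 (3.85) above, and ASN1 (-2.74), BT2 (-2.41), TCH4 (-2.40), LTL1 (-2.23) and CER1 (-2.15) below.

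Lists also differed in their change at 6 h, with median interactions of 0.567 for photosynthesis, 0.709 for aliphatic glucosinolates, -0.693 for camalexin, -0.469 for detoxification, -0.138 for pattern-triggered immunity, -0.371 for the jasmonate and ethylene set, -0.156 for flavonoids, -0.350 for salicylate and 0.120 for leaf polarity. Under scaling to the 75th percentile or processed signals the flavonoid and pattern-triggered immunity medians relative to all genes became 0.110 and 0.036, respectively. At 48 h the medians were 1.946 for detoxification, 1.314 for camalexin, 1.125 for jasmonate, 0.664 for pattern-triggered immunity, 1.037 for senescence, 0.974 for resistance to Botrytis, 0.961 for indole glucosinolates, 0.641 for phenylpropanoids, 0.244 for the jasmonate and ethylene set, -0.383 for the clock, -0.508 for leaf polarity, 0.323 for flavonoids, 0.236 for salicylate and 0.312 for ethylene. At 6 h the jasmonate and ethylene set (adjusted p = 0.0598 with an estimated correlation) and salicylate (adjusted p = 0.109 with an estimated correlation) lost their calls, and at 48 h salicylate did (adjusted p = 0.137 with an estimated correlation). Scaling to the 75th percentile ended the calls at 6 h of detoxification (adjusted p 0.749), flavonoids (0.644), salicylate (0.06) and the jasmonate and ethylene set (0.0569). At 48 h it ended those of the clock (0.219), ethylene (0.162) and phenylpropanoids (0.0665). Processed signals ended those at 6 h of pattern-triggered immunity (0.365), detoxification (0.169), the jasmonate and ethylene set (0.155) and flavonoids (0.0614), and at 48 h of salicylate (0.139) and ethylene (0.0642). The replicate block and slide as a fixed term ended that of salicylate at 48 h (0.0645 and 0.0717).

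Probes without a locus in the annotation, which no comparison used, also differed between the genotypes: of 2621 tested, 215 at 0 h, 692 at 6 h and 433 at 48 h.

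The first pattern is the response of drl1, smaller than that of the wild type at 6 h and larger at 48 h (spread ratios 0.795 and 1.289). At 6 h the values argue against normalization as the only cause, since the highest ratio under another scaling was 0.833. At 48 h the ratio ranged from 1.141 to 1.292 under other scalings. The larger response at 48 h kept its direction, but its size depended on the scaling, so normalization may contribute to it. The values also argue against slide or dye at 6 h (0.797 on one slide, 0.796 on the other), and against dye at 48 h (1.276 in Cy5, 1.289 in Cy3). Sampling of the genotypes at different times of day at 6 h stays open: the clock genes' own ratio was 0.894 with a jackknife error of 0.026, between that of all genes and 1. The 0 h samples enter both ratios. At 0 h the clock genes' genotype difference ran with the 6 h minus 48 h difference of the wild type (r = 0.755). Sampling at different times of day at 0 h therefore stays open too. A later response in drl1 stays open as a hypothesis without a test: the correlation of the genotype differences at 6 h and 48 h (r = -0.214) already follows from a smaller and then larger response. Other differences between the genotypes, such as in leaf shape or spread of the fungus, were not tested.

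The second pattern is that photosynthesis genes lay further below their 0 h level at 6 h than at 48 h in wild type (medians -0.896 and -0.321 by group means). Time of day may contribute, but this was not tested for the photosynthesis list. The root mean square change of clock genes at 6 h was 3.181 times that at 48 h, against 1.295 times over all genes. By the nominal times, 48 h falls at the time of day of 0 h and 6 h does not. A larger clock change at 6 h thus follows from the design and cannot decide the cause. Time of day alone, acting alike in both genotypes, is argued against by the median interaction of 0.567 for this list at 6 h. Without mock-inoculated leaves, infection and wounding cannot be weighed apart here, and neither was tested.

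The third pattern is the lower level of defence genes in drl1 at 0 h. A single slide or replicate is argued against, as the median of the pattern-triggered immunity list was -0.373 or lower in each same-numbered comparison (the others -0.456 and -0.460). Sampling of the genotypes at different times of day could account for part of it: across 17 clock genes the genotype difference at 0 h ran with the 6 h minus 48 h difference of the wild type (r = 0.755, Spearman 0.777, and 0.589 without CCA1 and LHY). Whether drl1 shifts the clock itself was not tested, so an effect of the mutation on defence genes stays open as a hypothesis.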

How the results depend on the processing

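Of the counts for the 9 comparisons, 187 values under an alternative stayed within 1.5 times the reported count and 23 did not. The cause of a change was not tested except where stated. A minimum of 2-fold, by construction, gave fewer genes: 326, 627 and 695 between genotypes at 0, 6 and 48 h, 3971 and 2193 in wild type at 6 and 48 h, 2356 and 3380 in drl1, and 546 and 1117 for the interactions at 6 and 48 h. Scaling to the 75th percentile gave, in that order, 996, 2823, 2154, 8078, 6380, 5212, 6686, 410 and 1744. A fit to only the groups of the comparison gave 4021 at 6 h between genotypes, and only Cy5 samples gave 3623 at 48 h.

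Leaving out each replicate in turn, with the lone or remaining samples assumed to vary like the other groups and the array correlation held, gave 2761 to 3104, 6532 to 7484 and 2801 to 5403 genes between genotypes at 0, 6 and 48 h. It gave 11840 to 12745 and 7268 to 9526 in wild type, 9198 to 10117 and 9623 to 11865 in drl1, and 2966 to 3922 and 2748 to 4127 for the interactions. The lowest values at 48 h came without wild type replicate 2 between genotypes, in wild type and for the interaction, and without drl1 replicate 2 in drl1. In these fits the 2 samples left in that group shared an array. DRL1 ranged from -2.678 to -2.57, -2.325 to -2.052 and -2.262 to -2.195. The replicate as a block gave 5132, 8978, 7348, 12965, 9690, 10457, 11828, 5048 and 5761, without the array effect between genotypes and for the interactions. Keeping outlier-marked spots gave 3940, 7919, 5788, 13108, 10051, 10680, 12126, 3900 and 4484, and at least 2 values per group 3519, 7247, 5241, 12069, 9200, 9792, 11166, 3442 and 3983; both were chosen after seeing the data.

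Of the tests of 25 lists in 9 contrasts 113 were called, and 110 with an estimated correlation, 106 under the 75th percentile, 108 with processed signals, 111 with the replicate block and 192 with fry, which does not compare a list with other genes. Heat shock at 0 h turned downward under the 75th percentile (adjusted p 0.0321; 0.0321 to 0.955 over its alternatives). With fry, indole glucosinolates at 6 h in wild type (9.79e-05) and the vascular list at 6 h in wild type (0.00776) and drl1 (1.76e-05) turned.

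The correlation of genotype differences between 0 h and 6 h was 0.509 under the 75th percentile, 0.4 with processed signals and 0.469 over called genes, and 0.413 to 0.439 leaving out replicates. Between 0 h and 48 h it was -0.257, reversed, under the 75th percentile and 0.113 with processed signals (0.074 to 0.101 leaving out replicates), and between 6 h and 48 h -0.272 and -0.086 (-0.231 to -0.193). The spread ratio was 0.83 and 0.833 at 6 h and 1.141 and 1.251 at 48 h under these scalings, and 0.791 to 0.801 and 1.278 to 1.297 leaving out replicates.

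Named genes reversed under the 75th percentile were 4CL3 (-0.008), EPF1 (-0.44) and GL2 (-0.349) at 0 h, CASP1 at 48 h (0.226), PHT1;4 in wild type at 6 h (-0.095), ACS2 (0.504), ELP4 (0.024), PRR3 (0.501) and HSP23.6 (0.168) for the interaction at 6 h, and NIMIN1 (0.25), EPF1 (0.555) and MYB106 (0.534) for that at 48 h. With the mean of probes RD29A at 0 h (0.117), GRX480 (0.084) and TSO2 (-0.244) at 6 h, PAL1 in wild type at 6 h (-0.19) and HSP90.1 for the interaction at 48 h (-0.134) reversed. With processed signals PROPEP3 (0.565), 4CL3 (0.158), LHY (-0.396) and PAD3 (2.119) did so for the interaction at 6 h, and VSP2 in drl1 at 48 h (0.424). Signal over background limits genes near the floor, whose folds are given as bounds.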

Other observations

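Several lists are not described in the report. The 10 measured genes of Elongator and tRNA modification were not called against other genes between genotypes: none changed at 0 h (median 0.05, list adjusted p 0.656) or at 48 h (list adjusted p 0.83), and at 6 h 3 fell (3 adjusted over the list alone, list adjusted p 0.153), where fry found a shift downward (adjusted p 2.55e-05). ELP4 differed by -0.42 ± 0.09. Heat shock genes were not called against other genes between genotypes (list adjusted p 0.957, 0.194 and 0.197 at 0, 6 and 48 h), while fry found them lower at 6 h and higher at 48 h (adjusted p 1.62e-05 and 0.00825). They rose over time in wild type, in 10 of 11 cases at 6 h and again at 48 h (10 adjusted over the list alone at each, list adjusted p 5.57e-07 and 2.07e-08). HSP70 rose by 5.74 ± 0.22 at 6 h and 2.86 ± 0.23 at 48 h. Ethylene genes rose at 6 h in wild type in 8 of 13 cases and fell in 3 (8 and 3 adjusted over the list alone, list adjusted p 0.0383, adjusted p = 0.0533 with an estimated correlation). Between genotypes at 0 h the ethylene list was not called (list adjusted p 0.0607) but was called as lower with the replicate block (adjusted p 0.0336). Abscisic acid and dehydration genes rose in drl1 at 48 h against wild type in 7 of 16 cases and fell in 1 (7 and 1 adjusted over the list alone, list adjusted p 0.0104). HAI1 differed by 2.25 ± 0.22 (n = 2 in drl1). Botrytis resistance genes were lower in drl1 at 0 h in 7 of 16 cases (8 adjusted over the list alone, list adjusted p 0.000177) and at 6 h in 8, with 1 higher (8 and 1 adjusted over the list alone, list adjusted p 0.042, adjusted p = 0.072 with an estimated correlation). That call at 6 h also ended under the 75th percentile, processed signals, the replicate block and slide as a fixed term (adjusted p 0.0535, 0.0841, 0.06 and 0.0507).

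Clock genes changed between genotypes in both directions at 0 h, with 5 of 17 up and 3 down (7 and 3 adjusted over the list alone, list adjusted p 0.364). LHY differed by -1.06 ± 0.11 and LUX by 0.81 ± 0.15. At 48 h 5 clock genes fell and none rose (5 down and 1 up adjusted over the list alone, list adjusted p 0.0205), a call that ended with processed signals (adjusted p 0.0795) and with the replicate block (adjusted p 0.0651). RVE1 differed by -1.26 ± 0.11. Among markers of other cell types in the genotype contrast at 0 h the stomatal list had 1 of 7 up (1 adjusted over the list alone, median 0.20, list adjusted p 0.0483, adjusted p = 0.0611 with an estimated correlation), and its median relative to all genes turned to -0.021 under scaling to the 75th percentile. There the trichome list (1 of 4 up, 2 up and 1 down adjusted over the list alone, list adjusted p 0.507) and the root list (0 of 5, list adjusted p 0.507) were not called. At 6 h the jasmonate list had a median of -0.21 and a mean of 0.08 between genotypes, with 3 of 26 up and 8 down (5 and 8 adjusted over the list alone, list adjusted p 0.491). At 0 h its 2 up and 6 down (2 and 8 adjusted over the list alone) gave a list adjusted p of 0.0607, and adjusted p = 0.0369 with an estimated correlation, 0.038 with the replicate block, 0.00696 with processed signals and 0.907 under the 75th percentile.

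After its group's mean was removed, every one of the 18 samples correlated best, among the samples of the other genotype at its time, with the one of its own number, and these also share slide and dye. Among samples of equal slide and dye, the same-numbered ones still correlated higher at each time.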
